A study of Mus musculus with 4 samples.

How the data were processed

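The series holds 4 RNA-seq libraries of mouse leukaemia stem cells, 2 with empty vector and 2 labelled TIFAB, grouped and numbered by their titles. The authors deposited a single table of 31363 genes. The submitters' processing notes name kallisto 0.44.0 and the mm10 build, without giving the role of either; the count model, filters and strand setting are not given in the sources used here. Per the file headers, each library has a column of its own, and the authors' table also gives a mean, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value per gene.

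The deposited library values are a normalized signal, estimated reads per gene divided by a size factor per library. This was read from the values, because 100% of the values in each library were whole multiples of one step (within 0.01 of a read), with steps of 0.946 and 0.992 for empty vector and 1.04 and 0.997 for TIFAB. The multiples summed to 52458833, 50534534, 49316489 and 51777267, and these sums are taken as the depth. The deposited mean signal equals the row mean of the 4 libraries. The authors' log2 fold change is positive where the libraries labelled TIFAB are higher. The deposited score is that fold change over its standard error. The authors' deposited p-value columns give an adjusted value for 22242 genes and none for 9121. In the floors, the exact intervals and the spread between libraries, too, 1 multiple is taken as 1 read. A count test was planned for a count table and another test for normalized values; the deposited values are normalized, so the latter was used, and no count test was run on the multiples.

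All 31363 versioned gene identifiers were found in the GENCODE vM21 annotation of GRCm38 (mm10), from which symbols, coordinates and transcript lengths were taken. Where a symbol belonged to several identifiers, the most abundant was used. Genes with a mean of at least 1 normalized read were tested on log2(value + 1) with limma 3.58.1 (limma-trend, group as the only term, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on that scale, which can understate the change of low genes, or overstate it where an arm's libraries are uneven. An exact permutation test of 2 against 2 libraries cannot go below a p of 0.333, so no such test was used. Figures were drawn with matplotlib 3.10.9.

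The 28 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the 28 lists), and the counts of members past the threshold are given over all genes and adjusted over the list alone. Camera called 13 lists, 5 higher and 8 lower. With an estimated correlation it called 0 after adjustment (smallest adjusted p 0.20) and 6 at an unadjusted p under 0.05, and fry, which asks only whether a list's genes move one way on balance, called 17. Named genes were a fixed set (Tifab, Hoxa9, Hoxa10, Meis1, Pbx3, Usp15, Trp53, Map3k14, Mki67 and the genes of the sort gate), the 12 genes with the largest changes in each direction among those past the threshold with separate groups and a mean of at least 5 CPM (the value scaled to its library's total) (leaving out predicted genes, pseudogenes and antigen receptor segments), and up to 4 members of each list past the threshold by smallest adjusted p; some genes that this rule takes are not reported here. A gene with 0 reads over an arm was given a fold against 3 reads over the arm and the lower limit of its 95% exact binomial interval, and one with 1 to 3 reads a ratio with its 95% exact binomial interval.

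Reads of near-identical genes can be split between copies. This concerns the Xlr, Ifi200, Ear, MHC class I, globin and heat shock Hspa1 families and the ribosomal protein genes with their pseudogenes, and these values are uncertain; antisense partners such as those in the Hoxa cluster cannot be told from their sense genes without a stated strand setting. For the mitochondrial protein genes, annotated transcripts of at least 99% identity over 80% of their length were sought with blastn 2.17.0.

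The libraries of an arm differed by more than sampling noise (chi-square per gene 13.3 with empty vector and 7.90 in the libraries labelled TIFAB), which does not show whether they came from separate animals. Beyond counting error their median spread was 5.09% and 3.99% of the mean over genes of 1000 or more normalized reads. Single genes can differ by more. The fit was tested on simulated data with the means and step sizes of these libraries and 200 changed genes among 26393 tested. All changed genes had a mean of at least 50 normalized reads, and noise was drawn independently for each library. The variance followed a single fixed function of the mean for all genes. The fit recovered 74.6% of the genes changed 1.6-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold, and 5.46% of its calls were false. These recovery rates do not cover genes of lower means, and none of the rates covers libraries that share an origin. Nor do the rates cover genes that differ in variance at the same mean, or as many changed genes as were called here. Alternatives tried were a replicate block, leaving out each library, other pseudocounts and filters, centring on library medians, other list tests and other thresholds; none of the library columns was left out.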

Results

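RNA was sequenced from leukaemia stem cells of mice carrying MLL-AF9 leukaemia, an acute myeloid leukaemia driven by a fusion of the KMT2A (MLL) histone methyltransferase with AF9. The donor cells came from bone marrow of animals carrying a NIK transgene, were transduced with MLL-AF9, and then received either an empty retroviral vector or one carrying TIFAB, a forkhead-associated-domain protein known to restrain TRAF6 signalling. Lineage-negative, c-Kit-positive, Sca1-negative, CD16-positive, CD34-positive cells were sorted from animals with overt leukaemia. Each arm had 2 libraries. The deposited values were whole multiples of one step per library, and the multiples summed to 52458833 and 50534534 reads in the empty-vector libraries and to 49316489 and 51777267 in those labelled TIFAB. At this depth, 3 reads correspond to 0.0572 to 0.0608 CPM.

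The transduced gene was examined first because it checks the labels. Mouse Tifab (ENSMUSG00000049625.6, chromosome 13, 56173704 to 56178885 on GRCm38) stood at 15630.3 ± 515 normalized reads (SD, n = 2) with empty vector and at 11657 ± 134 (SD, n = 2) in the libraries labelled TIFAB. It was thus 1.34-fold lower in the libraries labelled TIFAB, with a log2 change of -0.42 ± 0.05 (SE) and an adjusted p of 2.3e-05 by limma-trend. The labels do not say from which species the vector's TIFAB sequence came or whether the values include it. Because this gene went against the label, the arm is called the libraries labelled TIFAB throughout, and every direction given here rests on those labels. Usp15, which encodes a deubiquitinase known to bind TIFAB, had values of 5146 ± 442 and 5097 ± 96.4 normalized reads (SD, n = 2 each) and did not pass the test (limma-trend adjusted p 0.93).

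The series title names HOXA9 as the route by which TIFAB acts, so the Hoxa genes were compared next. Hoxa9, the homeobox gene on which MLL-rearranged leukaemias depend (ENSMUSG00000038227.15, chromosome 6, 52223100 to 52231089), was 2.82-fold higher in the libraries labelled TIFAB, at 23776 ± 47.6 against 8426 ± 388 normalized reads (SD, n = 2 each). Its log2 change was 1.497 ± 0.0496 (SE), with an adjusted p of 2.3e-10 by limma-trend. Hoxa10, its neighbour at 52231197 to 52240854, was 2.25-fold higher and Meis1, which encodes the DNA-binding partner of HOXA9, was 1.73-fold higher. Pbx3, another partner, stood at 6679 ± 387 and 7082 ± 82.4 normalized reads (SD, n = 2 each) and did not pass (adjusted p 0.35). Without any single library the log2 change of Hoxa9 lay between 1.45 and 1.54 and that of Tifab between -0.46 and -0.39, and neither passed the threshold any longer: without Con replicate 1 or 2 both had adjusted p values of 0.088 and 0.091, without TIFAB replicate 1 they were 0.066 for Hoxa9 and 0.13 for Tifab, and without TIFAB replicate 2 they were 0.056 and 0.12. With a mean of at least 50 normalized reads, a filter chosen after the data were seen, both passed in all 4 omissions, with the same log2 changes (adjusted p 6.6e-10 to 3.4e-09 for Hoxa9 and 3.1e-05 to 0.00036 for Tifab).

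**Figure D1:**
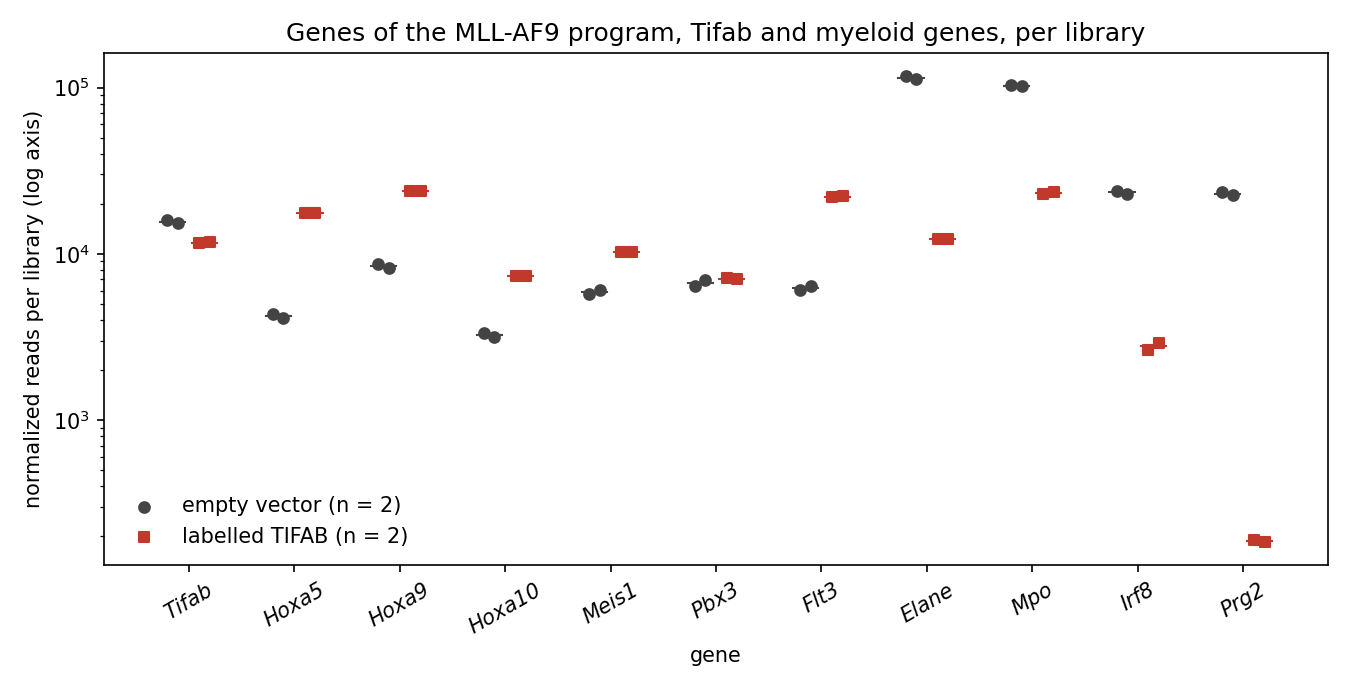
Normalized reads per library on a log axis for 11 genes, with each arm's 2 libraries as points and their mean as a short line. Hoxa5, Hoxa9, Hoxa10, Meis1 and Flt3 lay higher in the libraries labelled TIFAB, Tifab, Elane, Mpo, Irf8 and Prg2 lay lower, and Pbx3 did not pass the test (adjusted p 0.35).

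Myeloid differentiation genes fell and several Hoxa genes and Flt3 rose in the libraries labelled TIFAB. The homeobox gene Hoxa5 went from 4204 ± 164 to 17647 ± 4.90 normalized reads (SD, n = 2 each), a 4.20-fold rise, and the receptor tyrosine kinase gene Flt3 rose 3.52-fold. Prg2, which encodes the eosinophil major basic protein, fell from 22991 ± 633 to 187 ± 3.65 normalized reads, and the neutrophil elastase gene Elane fell 9.42-fold from 114830.0 ± 2853. In all, 3408 of 27492 genes were higher and 3735 were lower at an adjusted p under 0.05 by limma-trend, and 1350 and 1290 of them changed at least 2-fold. Of the calls, 47.7% were higher, and with log values centred on library medians this share was 35.6% (2517 higher, 4560 lower). Leaving out Con replicate 1, Con replicate 2 or TIFAB replicate 1 left 0 genes past the threshold, with 7739, 7620 and 7054 at an unadjusted p under 0.05, and leaving out TIFAB replicate 2 left 1168 higher and 412 lower; with a mean of at least 50 normalized reads, these 4 omissions left 2585 to 3063 higher and 3017 to 3409 lower. The labels do not say that an arm's libraries came from separate animals, so the p values measure only the spread between these samples, which may be technical.

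The genes that rose most were nearly silent with empty vector. Slitrk6, which encodes a neuronal transmembrane protein, had 0 reads in both empty-vector libraries and 1225 ± 38.3 normalized reads (SD, n = 2) in those labelled TIFAB. Slitrk6 was 844-fold higher when the floor is taken as 3 reads over the arm, with a 95% exact binomial lower limit of 686. Xlr3b had 2 reads against 5395, a ratio of 2839 (95% exact binomial interval 785 to 23445), but the Xlr family has near-identical members on the X chromosome and its values are uncertain. Nol4 had 3 reads against 3627, a ratio of 1272 (interval 435 to 6172), Ppp1r14c 1 against 1723, a ratio of 1813 (interval 325 to 71655), and Itm2a 2 against 1019, a ratio of 536 (interval 148 to 4433). Stra6, the receptor for retinol-binding protein, rose 765-fold and Rbp4, retinol-binding protein itself, rose 301-fold, from 15.9 ± 6.996 to 4852 ± 43.8 normalized reads (SD, n = 2 each). Six4 rose 482-fold, from 5.39 ± 3.60 to 2823 ± 116 normalized reads, and lies on chromosome 12 at 73099609 to 73113456. The Wnt receptor gene Fzd8 rose 388-fold, Unc13c 335-fold, Fam155a 227-fold and Colq 219.7-fold, all on the log2(value + 1) scale. That scale can understate changes of low genes, or overstate them where an arm's libraries are uneven. The latter holds for Fzd8, at 2.84 ± 4.01 against 1006 ± 136 normalized reads (SD, n = 2 each). The adjusted p of these 12 genes was at most 7.2e-07 by limma-trend. Intervals and floors cover counting error only.

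The genes that fell most were nearly silent in the libraries labelled TIFAB. Xlr had 1737 reads with empty vector and 0 in both libraries labelled TIFAB, 550.2-fold lower against the same floor (exact lower limit 447), with the same uncertainty as Xlr3b. The macrophage adhesion receptor gene Adgre4 had 2462 reads against 1, a ratio of 2339.6 (95% exact binomial interval 419.5 to 92448). Ldhb, a lactate dehydrogenase subunit, had 1805 against 1, a ratio of 1715 (interval 307 to 67788), the Y-linked RNA helicase gene Ddx3y 1658 against 1, a ratio of 1576 (interval 282 to 62270), and Stxbp6 1278 against 1, a ratio of 1214 (interval 218 to 48007). Pax5, the master regulator of B-cell identity, fell from 2808 ± 62.5 to 3.04 ± 1.35 normalized reads (SD, n = 2 each), 716-fold. The actin-severing protein gene Scin fell 170.0-fold, from 3790 ± 43.6 to 22.3 ± 9.39 normalized reads, and the interferon-inducible Ifi213, a member of a family of close paralogs, fell 152-fold. Lipo3 fell 212-fold, Adamts2 211-fold, Tmem178 191-fold and Rnf17 183-fold. For Rnf17 the log2(value + 1) scale can overstate the change, since its libraries labelled TIFAB were uneven. It stood at 916 ± 151 normalized reads with empty vector and 6.23 ± 7.40 in those labelled TIFAB (SD, n = 2 each). The adjusted p of these 12 genes was at most 1.4e-06 by limma-trend. Like Ddx3y, the Y-linked genes Kdm5d and Uty had 301 and 303, and 146 and 150 reads with empty vector. In the libraries labelled TIFAB they had 5 and 0, and 0 and 0, and Y-linked Eif2s3y had at most 1 read in any library. The Ddx3y ratio may thus reflect the sex or origin of the cells rather than a change in expression, which was not tested.

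The lists of differentiated myeloid genes fell together. Of 25 granule protein genes of neutrophils and their precursors, 20 fell, 3 rose and 2 did not pass (21 fell and 3 rose when adjusted over the list alone). Elane, Chil3, which encodes a chitinase-like lectin, and the myeloperoxidase gene Mpo fell, with log2 changes of -3.23, -3.20 and -2.14, and the gelatinase gene Mmp9 fell by 6.21. The members that rose were Ctsg, Pglyrp1 and Ly6g, named after their values were seen, by 0.99, 1.13 and 3.08. The list's median log2 change was -1.97, with a camera adjusted p of 2.4e-18, and adjusted p = 0.20 with an estimated correlation. Of 26 monocyte and macrophage genes, 20 fell, 4 rose and 2 did not pass (21 and 4 adjusted over the list alone), with a median of -1.96, a camera adjusted p of 1.2e-11, and adjusted p = 0.20 with an estimated correlation. Irf8, which encodes a transcription factor that directs monocyte fate, the M-CSF receptor gene Csf1r, Mpeg1 and F13a1 fell, with log2 changes of -3.08, -3.06, -2.35 and -1.84. Of 8 eosinophil markers, 7 fell and 0 rose (8 fell adjusted over the list alone), among them Prg2, Prg3, Siglecf and Epx, with log2 changes of -6.93, -4.70, -2.98 and -4.79. Their camera adjusted p was 6.3e-10, and adjusted p = 0.20 with an estimated correlation. Of 11 mast cell and basophil markers, 5 fell, 1 rose and 5 did not pass, with the same counts adjusted over the list alone. Gata2, the histidine decarboxylase gene Hdc and Il6ra fell, with log2 changes of -1.23, -1.19 and -1.02, and the basophil protease gene Mcpt8 rose by 1.22. The camera adjusted p was 0.0075, and adjusted p = 0.27 with an estimated correlation, and the list did not pass without Con replicate 1 (0.055), TIFAB replicate 1 (0.087) or TIFAB replicate 2 (0.066).

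**Figure D2:**
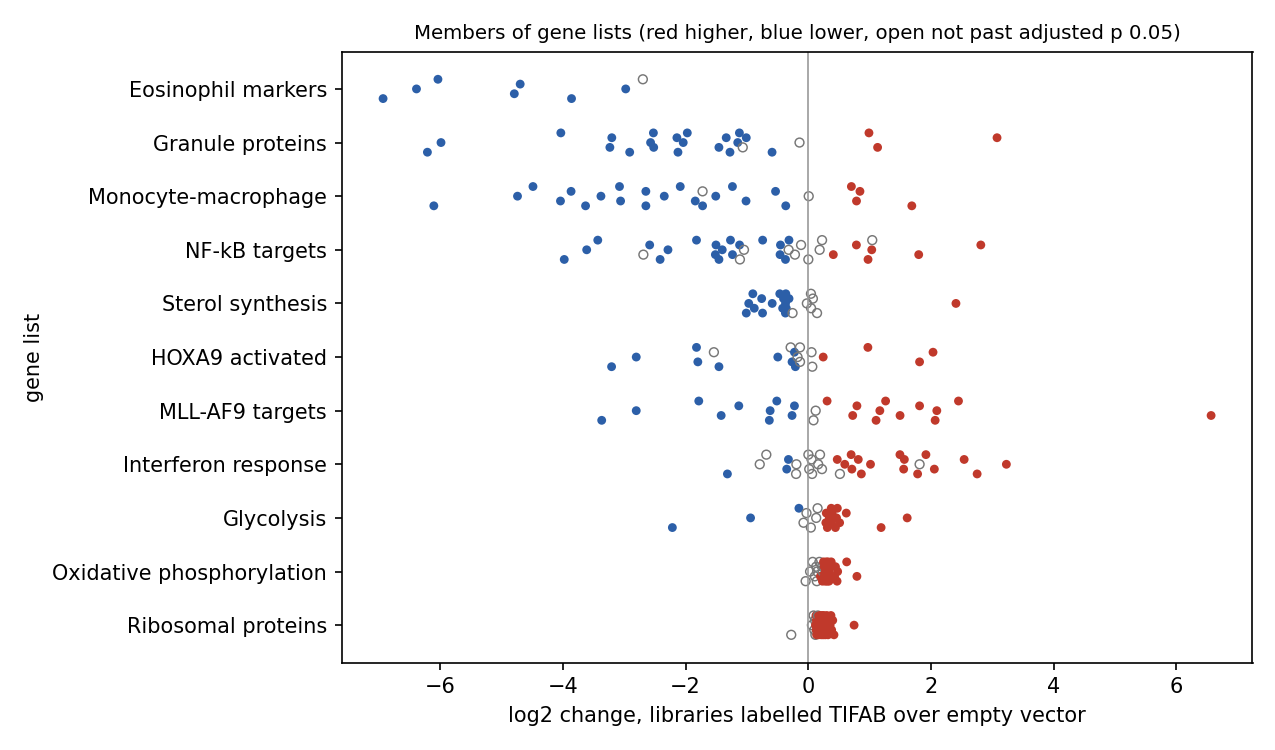
Log2 change of each member of 11 gene lists in the libraries labelled TIFAB over empty vector, with higher calls in red, lower calls in blue and members that did not pass adjusted p 0.05 open. Of 25 granule protein genes 20 lie below 0 as calls, while 35 of 42 ribosomal protein genes lie above 0 as calls within a narrow range.

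Lists of the leukaemia program went both ways. Of 24 targets of MLL fusion proteins, 12 rose, 10 fell and 2 did not pass (13 and 10 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p 0.074, and adjusted p = 0.33 with an estimated correlation), but was called higher by fry (adjusted p 0.0040). Hoxa5 and Flt3 rose by 2.07 and 1.82 on the log2 scale, and Tcf4 fell by 3.37. Of 20 genes that HOXA9 is known to activate, 4 rose, 9 fell and 7 did not pass (4 and 12 adjusted over the list alone). Dach1, the anti-apoptotic gene Bcl2 and the chemokine gene Ccl3 fell, with log2 changes of -3.21, -2.81 and -1.82, while Flt3 rose. Its camera test called the list lower (adjusted p 0.027, and adjusted p = 0.29 with an estimated correlation), and it did not pass without Con replicate 1 or 2 (adjusted p 0.084 and 0.073) or TIFAB replicate 1 or 2 (0.060 and 0.075), nor with a mean of at least 5 or 50 normalized reads (0.073 and 0.19). Of 20 genes tied to self-renewal of MLL-rearranged leukaemia, 7 rose, 7 fell and 6 did not pass, also adjusted over the list alone (camera adjusted p 0.94). Sox4 rose by 2.04 while Mef2c and the integrin gene Itgb3 fell, with log2 changes of -1.79 and -1.095. Of 17 stem and progenitor genes, 4 rose, 3 fell and 10 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.77); Hoxb4 fell by 4.02 and Gata2 fell by 1.23 while Txnip rose by 0.97, and the list's median and mean were negative where its test pointed up.

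Among genes of NF-kB and Toll-like receptor signalling, the pathways TIFAB is known to act on, more fell than rose. Of 35 NF-kB targets, 19 fell, 6 rose and 10 did not pass (21 and 7 adjusted over the list alone), with a camera adjusted p of 0.00066, and adjusted p = 0.22 with an estimated correlation and 0.063 with a mean of at least 50 normalized reads. Ccl3 and Tnfaip2 fell, with log2 changes of -1.82 and -2.42, whereas the stress gene Gadd45b and the cytokine gene Tnf rose by 2.81 and 1.80. The other members that rose were Nfkbia, Icam1, Irf1 and Nfkbiz, named after their values were seen, by 0.79, 1.04, 0.98 and 0.41. Of 32 genes of the Toll-like receptor and TRAF6 pathway, 15 fell, 3 rose and 14 did not pass (19 and 3 adjusted over the list alone), with a camera adjusted p of 3.9e-05, and adjusted p = 0.33 with an estimated correlation. The co-receptor gene Cd14, also a monocyte marker, fell by 4.04, and Map3k14, which encodes NIK, fell by 0.92. The kinase genes Irak3 and Irak2 fell, with log2 changes of -2.39 and -0.98. Traf6 itself, named after its value was seen, changed by 0.005 and did not pass (limma-trend adjusted p 0.98). Whether the falls in these lists come from TIFAB acting on the pathways was not tested. The donor animals carried a NIK transgene, and the labels do not say whether the Map3k14 value includes it. Of 29 p53 targets, 12 fell, 6 rose and 11 did not pass, also adjusted over the list alone (camera adjusted p 0.24). Cdkn1a, the p21 cell-cycle inhibitor, and the pro-apoptotic gene Bbc3 fell, with log2 changes of -0.90 and -0.98, and Plk2 and Sesn2 rose by 4.37 and 1.72. Trp53 itself fell by 0.17 (limma-trend adjusted p 0.047). Of 32 interferon-stimulated genes, 16 rose, 3 fell and 13 did not pass (18 and 3 adjusted over the list alone), with a camera adjusted p of 8.6e-05, and adjusted p = 0.21 with an estimated correlation; Irf7, Oasl2 and Ifih1 rose by 2.54, 3.23 and 1.02. Of 10 MHC class II genes, 4 rose, 3 fell and 3 did not pass, also adjusted over the list alone (camera adjusted p 0.67). H2-Ob and H2-Oa rose by 1.46 and 1.42, Cd74 fell by 3.53, and the list's median of -0.14 and mean of -0.43 were negative where its test pointed up.

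Most ribosomal protein and respiratory genes rose, by small amounts. Of 42 ribosomal protein genes, 35 rose and 0 fell (39 and 0 adjusted over the list alone), with a median log2 change of 0.21, a camera adjusted p of 7.6e-14, and adjusted p = 0.27 with an estimated correlation. Rpl3 and Rps23 rose by 0.42 and 0.36. Of 34 nuclear genes of oxidative phosphorylation, 24 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 0.29, a camera adjusted p of 1.4e-10, and adjusted p = 0.22 with an estimated correlation; Ndufa4 rose by 0.79. With log values centred on library medians, the ribosomal median was 0.12 and the respiratory median 0.20. Log2 changes were lower for long transcripts, with a median of 0.02 for 4054 protein-coding genes with a median transcript length under 1000 nt and -0.15 for 688 over 4000 nt. The medians of 10000 random lists matched on length and expression centred on 0.11 for the ribosomal list, whose own median lay at percentile 98.85 of them. They centred on 0.02 for the respiratory list, whose median lay at percentile 100. Each list's own members stayed in the pool that was drawn from, which can pull these centres towards the list. The centres therefore do not measure length and expression alone. Of 22 glycolytic and hypoxia-induced genes, 14 rose, 3 fell and 5 did not pass, also adjusted over the list alone (camera adjusted p 6.6e-06, and adjusted p = 0.21 with an estimated correlation). Egln3 and Vegfa rose by 1.61 and 1.19, and the glucose transporter gene Slc2a3 and the hexokinase gene Hk2 fell, with log2 changes of -2.22 and -0.94. Of 22 genes of sterol synthesis and uptake, 15 fell, 1 rose and 6 did not pass, also adjusted over the list alone (median -0.37, camera adjusted p 1.9e-05, and adjusted p = 0.21 with an estimated correlation). The sterol transport gene Stard4 and Hsd17b7 fell, with log2 changes of -0.88 and -0.90.

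Of 35 cell cycle genes, 13 fell, 6 rose and 16 did not pass (14 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p 0.29), but was called lower by fry (adjusted p 0.039) and with log values centred on library medians (0.017). Mki67, the proliferation marker, fell 1.83-fold, from 41310.4 ± 5464 to 22508 ± 694 normalized reads (SD, n = 2 each), and the mitotic genes Cenpf and Kif11 fell, with log2 changes of -0.997 and -0.496, while the replication licensing gene Mcm3 rose by 0.44. Of 30 MYC targets, 8 rose, 4 fell and 18 did not pass, also adjusted over the list alone (camera adjusted p 0.87). Odc1 rose by 0.90 and Srm fell by 0.59, and the list's median of -0.04 was negative where its test and mean pointed up. Of 22 genes of the integrated stress response, 4 rose, 7 fell and 11 did not pass (6 and 7 adjusted over the list alone; camera adjusted p 0.67). The chaperone gene Hspa5 rose by 1.16 and the serine synthesis gene Phgdh fell by 1.30; the list's mean of 0.12 was positive where its median and test were negative. Of 24 immediate early and heat shock genes, 10 rose and 11 fell (11 and 12 adjusted over the list alone; camera adjusted p 0.79), among them Fos and Klf2, with log2 changes of -1.78 and -1.92, and Dusp2 and Dnajb1, which rose by 2.05 and 1.42.

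Of the 13 protein-coding mitochondrial transcripts, 12 rose and 0 fell (13 adjusted over the list alone), and the share of mitochondrial transcripts was 1.66% and 1.88% with empty vector and 3.49% and 3.34% in the libraries labelled TIFAB. mt-Nd1, mt-Nd5, mt-Co1 and mt-Nd4 rose by 1.07, 0.90, 1.003 and 1.12 on the log2 scale. The list's camera adjusted p was 9.9e-13, and adjusted p = 0.33 with an estimated correlation. For 6 of the 13 genes (mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l) the empty-vector libraries differed from each other 5.27- to 30.2-fold, and without these genes the list's median was 0.90 instead of 1.12.

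Most markers of other cell types lay below 1 CPM. Of 12 B cell markers, 2 rose and 3 fell; besides Pax5, Cd79a fell by 3.92 and Cd79b rose by 0.47 on the log2 scale. Of 14 T and NK cell markers, 3 rose (Nkg7, Lck and Prf1, by 1.58, 3.18 and 4.22) and 0 fell; the median and mean were negative where the test pointed up. Of 15 erythroid markers, 2 rose, Tfrc, the transferrin receptor gene, by 1.42 and Hbb-bs by 2.55. Of 10 megakaryocyte markers, Itga2b and Vwf fell, with log2 changes of -2.51 and -1.31, and F2rl2 rose by 1.91. Of 13 dendritic cell markers, 4 rose (Flt3, Itgax, Cox6a2 and Ccr7) and 1 fell, and of 12 stromal and endothelial markers 3 fell (Col1a1, Pecam1 and Kitl). All of these counts were the same adjusted over the list alone, and these 6 lists did not pass as a whole (camera adjusted p 0.47, 0.62, 0.11, 0.59, 0.23 and 0.62). Some did under other settings: by fry the B cell list lower and the dendritic cell list higher (adjusted p 0.026 and 0.0040), with centring the erythroid list higher (0.042), and with a mean of at least 50 normalized reads the T and NK and dendritic cell lists higher (0.012 and 0.0072), with 2 members each. A mean of 1 CPM was reached by 4, 2, 2, 3, 2 and 2 of their members.

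The genes behind the sort gate were read as a description of the sorted cells. Kit fell by 0.16 on the log2 scale (limma-trend adjusted p 0.032) and Fcgr3, which encodes CD16, fell by 0.24 (adjusted p 0.0020). Cd34 stood at 7461 ± 116 and 6795 ± 86.4 normalized reads (SD, n = 2 each) and Fcgr2b at 7825 ± 25.1 and 8253 ± 47.7, and neither passed (adjusted p 0.086 and 0.33). Ly6a, which encodes Sca1, had 5 and 5 reads with empty vector and 2 and 3 in the libraries labelled TIFAB.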

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

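The filter at a mean of 50 normalized reads, alone and with each library left out, the mitochondrial list without 6 genes, and the authors' deposited adjusted p were added after seeing the data. The counts of 3408 higher and 3735 lower genes stayed within 1.5 times under other pseudocounts (2972 to 3580 and 3331 to 3896), other filters (2725 to 3674 and 3081 to 3984), centring (2517 and 4560), an adjusted p under 0.1 (4139 and 4368) and the authors' deposited table (3115 and 3495). Requiring a 2-fold change left 1350 and 1290. Without 1 library, limma-trend called 0 to 1168 higher and 0 to 412 lower genes, with 7054 to 7739 at an unadjusted p under 0.05. The limma prior degrees of freedom fell from 10.2 to between 0.79 and 0.95 in these fits, and with a mean of at least 50 they stayed between 9.25 and 13.2, with 2585 to 3063 higher and 3017 to 3409 lower genes. The log2 change was -0.46 to -0.39 for Tifab and 1.45 to 1.54 for Hoxa9 without 1 library; an arm left with 1 library is assumed to vary like the other. Same-numbered replicates did not deviate together (correlation of deviations across genes -0.04). This gives no sign of pairing by number, but a correlation across all genes cannot exclude it. A replicate block gave 3753 higher and 4015 lower genes, with -0.42 for Tifab and 1.497 for Hoxa9. With the block, camera called MLL-AF9 targets (adjusted p 5.3e-07) and dendritic cell markers (0.024) higher and B cell markers (0.011) lower. The limma prior degrees of freedom were infinite there, so each gene's variance was replaced by the trend over all genes. The p values with the block therefore do not reflect the spread of single genes. Of the other 133 named genes, 128, 128, 128 and 74 lost the threshold without Con replicate 1, Con replicate 2, TIFAB replicate 1 and TIFAB replicate 2, and 1, 1, 2 and 2 of the 125 tested did so at a mean of at least 50. Usp15 ranged from -0.0990 to 0.0764 without 1 library, turning to 0.0764 without Con replicate 2 and 0.00802 without TIFAB replicate 2 (also at a mean of at least 50), and Pbx3 and Fcgr2b turned to -0.00311 and -0.0119 with centring, none past the threshold.

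Camera's 5 higher and 8 lower lists became 0 and 0 with an estimated correlation, and 8 higher without TIFAB replicate 2 at a mean of at least 50; the cause was not tested. T and NK and dendritic cell markers, with 2 members each, were called higher at a mean of at least 50 with all libraries and without each of the 4 (adjusted p 0.0097 to 0.014 and 0.0055 to 0.0086), as were erythroid markers there without TIFAB replicate 2 (0.048). NF-kB targets did not pass there (0.063) nor without Con replicate 1 (0.13), Con replicate 2 (0.061) or TIFAB replicate 2 (0.066). Lists that passed neither as reported nor in the fit named turned the direction of their test, with these medians: with the replicate block, LSC program (-0.0627), p53 targets (-0.180) and integrated stress response (-0.0770); with fry, integrated stress response (-0.0770) and stem and progenitor (-0.161); without 1 library, MYC targets (-0.0533 to 0.00206), immediate early and heat shock (-0.109 to -0.0183), MHC class II (-0.248 to -0.0381), stem and progenitor (-0.00939 to 0.0331) and T and NK (-1.36 to 0.195); with no filter, MYC targets (-0.0414); with centring, MYC targets (-0.130); with a mean of at least 5 or 50, LSC program (0.0227). At a mean of at least 50, the LSC program stood at 0.0324 without Con replicate 1, 0.0129 without Con replicate 2, 0.0265 without TIFAB replicate 1 and 0.0137 without TIFAB replicate 2, and the immediate early list at -0.0183 without Con replicate 1 and -0.0841 without TIFAB replicate 2. Alternatives planned for count tables were not run, because the deposited values are normalized. Depth limits genes near 3 reads per arm, for which no difference can be told from counting error.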

Other observations

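The gene groups and tests in this part were chosen after the values were seen, except the test that adds nuclear copies to the mitochondrial genes of both arms, which was fixed before their values were seen. The rise of Hoxa9 extended over its cluster on chromosome 6. Of 12 Hoxa genes and antisense partners, 11 rose and 0 fell by limma-trend in the libraries labelled TIFAB. Hoxa4 rose by 2.40 on the log2 scale, Hoxa6 by 2.10, Hoxa3 by 1.79 and Hoxa7 by 1.11, and the antisense genes Hoxaas3 and Hoxaas2 by 2.34 and 1.77. Hoxa13 had 5.98 normalized reads in 1 library and 0 in the other 3. All 4 inhibitor-of-DNA-binding genes rose, Id1 by 1.62, Id2 by 2.45, Id3 by 5.84 and Id4 by 2.62, the latter 2 from at most 5.67 normalized reads in either empty-vector library.

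Of 15 genes of MHC class I antigen presentation, 11 rose and 2 fell. H2-K1 rose by 0.60 on the log2 scale, B2m, the class I light chain gene, by 0.35, the peptide transporter genes Tap1 and Tap2 by 0.39 and 0.81, and the immunoproteasome genes Psmb8 and Psmb9 by 0.32 and 0.45, while H2-T23 fell by 0.215 and Tapbp fell by 0.192. Of 12 Kruppel-like factor genes, 9 fell and 1 rose; Klf2, Klf6 and Klf9 fell, with log2 changes of -1.92, -1.41 and -1.31, and Klf10 rose by 0.24. Of 17 integrin genes, 11 fell and 3 rose. Itga1, Itga9 and Itgb7 fell, with log2 changes of -3.92, -5.60 and -1.81, and Itgb4, Itgal and Itgax rose by 2.94, 0.62 and 1.11.

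Mouse Tifab was lower, not higher, in the libraries labelled TIFAB. A rise of at least 1 on the log2 scale would have argued against a vector sequence that the mouse gene's value leaves out; the change was -0.42, which leaves this open, since the cells' own gene could respond in either direction. With exchanged labels and a vector counted on the mouse gene, a difference of at least 2-fold in favour of empty vector was predicted and no more than 1.1-fold otherwise; the observed 1.34-fold lies between, and Hoxa9, which the series title says TIFAB raises, was 2.82-fold higher in the libraries labelled TIFAB, though that title may rest on the same labels. These explanations cannot be told apart from these values, because no vector or human sequence was analysed here. An effect of TIFAB on the cells' own gene also stays open and was not tested.

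For 6 neighbouring mitochondrial genes, from mt-Co2 at 7013 to mt-Nd4l ending at 10173, the median log2 change was 2.82, against 0.90 for the other 7, a difference of 1.92 that rests on Con replicate 1 (0.55 without it, with medians of 1.42 and 0.87, and 3.34 without Con replicate 2). In Con replicate 1 these genes were 5.27- to 30.2-fold lower than in Con replicate 2 (mt-Atp6 at 974 and 29459 normalized reads), and with the values of their annotated nuclear copies added the median ratio was still 5.67, which argues against a split of reads between the genes and these copies as the source of that deficit. Between the arms, such a split needs copies that fall in the libraries labelled TIFAB, but their sum rose by 0.93 ± 0.11 (SE) on the log2 scale (3 of the 5 copies rose and 0 fell) and adding them left a difference of 1.75 (0.54 without Con replicate 1), which argues against it there too; one larger share of mitochondrial RNA in the libraries labelled TIFAB stays open, since the difference of 0.55 lies between the limits set (0.3 or less if so, at least 1 if not). Of the 6 genes, 5 have an annotated nuclear copy of at least 99% identity over 80% of their length, and 0 of the other 7 do, so reads that match both places may have been lost before deposit; mt-Atp8, which has no such copy, was also 7.01-fold lower in Con replicate 1, which leaves this open. A biological explanation was not tested.

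At 0 to 3 reads over one arm and over 250 normalized reads in each library of the other stood 23 genes, 14 on in the libraries labelled TIFAB and 9 on with empty vector. Cells of the other sex in an arm would not alone account for the set, since 22 of the 23 genes lie on chromosomes other than Y. Such cells beside another difference between the arms are not excluded. The candidate explanation that each arm's libraries come from 1 leukaemia or donor pool, so that the arms differ by clone, cannot be told apart from an effect of TIFAB, because the labels name no animal. The median spread between an arm's libraries beyond counting error was 5.09% of the mean with empty vector and 3.99% in those labelled TIFAB. It was taken over genes of 1000 or more normalized reads, and single genes can differ by more. A median of 20% or more would have argued against a shared origin of an arm's libraries. Of 4 Y-linked genes, Eif2s3y had at most 1 read in any library. Ddx3y, Kdm5d and Uty had 785 and 873, 301 and 303, and 146 and 150 reads with empty vector. In the libraries labelled TIFAB they had 1 and 0, 5 and 0, and 0 and 0. Xist had 76709 and 84007 reads with empty vector and 112513 and 119859 in the libraries labelled TIFAB, a log2 change of 0.61. The empty-vector libraries thus held both Xist and Y-linked reads. For Ddx3y, Kdm5d and Uty the arms differed, with reads in both empty-vector libraries and almost none in those labelled TIFAB. The arms may therefore differ in the sex or origin of their cells apart from TIFAB, which was not tested. Any such difference would go along with TIFAB in every comparison here.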
